A study of Homo sapiens with 18 samples.

How the data were processed

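RNA of peripheral blood mononuclear cells was sequenced from the 3′ end, with molecular identifiers added to the reads, in 6 donors with high and 3 with low Lp(a), each untreated and after 2 h of LPS. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.5.0, aligned to GRCh38 with STAR 2.6.0 and counted per gene with featureCounts. The annotation release, the version of featureCounts, the use of the molecular identifiers and any filter are not given in the sources used here. The values the authors deposited are CPM, for 60671 gene rows in 18 libraries. In each library 100% of the nonzero values were whole multiples of the value of 1 read within 0.0051 CPM, so reads were recovered from them. One read was worth 0.352 to 0.529 CPM, and libraries held 1890210 to 2839472 reads in genes. Whether these are reads or molecules is not known, and the floor of 3 reads covers counting error only.

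Samples were grouped by their labels. The 507 rows of Y-linked genes, XIST and TSIX were left out of every test, and 1094 rows share a symbol with another row. Genes with at least 1 CPM in at least 3 of the 18 libraries were tested (17151), as log2(CPM + 1), with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 and Benjamini-Hochberg adjustment at 0.05. The effect of LPS in each group of donors and the difference of these effects came from 1 fit of all 18 libraries with 4 group means. High and low Lp(a) were compared in the 9 libraries of a treatment. The labels number the replicates without stating a pairing. Within each Lp(a) group, the untreated and LPS libraries of the same number deviated from their group means together (correlation across genes 0.253 to 0.581, above that with every other number for 8 of 9 donors; low Lp(a) replicate 1 had 0.257 with another). The numbers were therefore read as donors, and the counts of genes and lists with the donor as a block stand beside those without it.

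The 26 gene and marker lists of the report were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists of a comparison. The mean log2(CPM + 1) of each list in each donor was compared with a two-sided exact permutation test over the 84 choices of 3 of 9 donors. The genes named are, for each comparison, up to 3 called members of each list with the largest change or, with none called, the member with the smallest p; the 5 largest rises and falls among called genes with a mean of at least 5 CPM in a compared group, moving the same way in every donor for LPS; and a fixed set of genes in every comparison, given here in part. Left out of this rule were genes whose level often reflects an inherited deletion, copy number or allele, antigen receptor segments and unnamed loci. The text gives the members with the smallest p only in part. The groups, tests, lists, this rule and the alternatives, except as stated, were chosen before the data were examined.

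The genes with most detail are protein-coding and lie, in GENCODE 29 on GRCh38, on chromosome 1 at 94529225 to 94541800 (F3) and 206767602 to 206772494 (IL10), chromosome 2 at 112829751 to 112836903 (IL1B), chromosome 7 at 22725884 to 22732002 (IL6), chromosome 17 at 34255218 to 34257203 (CCL2) and chromosome 18 at 63871692 to 63903890 (SERPINB2). GENCODE 29 held 54519 of the table's symbols.

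Alternatives were pseudocounts of 0.25 and 5, no filter and a filter of 5 CPM, median-of-ratios scaling, quantile normalization, robust variances, edgeR 4.0.16 (quasi-likelihood, recovered reads), the donor as a block or random effect, a monocyte marker covariate, only the libraries compared, and leaving out each donor. Where this leaves fewer low Lp(a) donors, their spread is pooled with that of the other groups. Chosen after the data were seen were the blocked difference of responses as a result of its own, low Lp(a) replicates 1 and 2 averaged and counted as 1, and an immediate early and heat shock covariate. Replicates were compared by the chi-square of reads over genes with at least 20 reads in the pair. The tests were tested on simulated negative binomial reads with 200 genes of at least 5 CPM changed and no donor effect. Of genes changed 4-fold, limma called 96.1% for LPS in high Lp(a), 80.3% for LPS in low Lp(a), 82.2% and 83.3% for high against low Lp(a) untreated and with LPS, and 56.5% for the difference of responses. Of genes changed 2-fold it called 36.4%, 12.2%, 9.09%, 21.3% and 1.37%. Of all its calls 3.57%, 4.96%, 8.09%, 4.79% and 3.19% were false, where 5% was aimed at. Genes were drawn independently and fitted without the block. These rates therefore do not give the share of false calls in the real libraries or with the block. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.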

Results

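Gene expression was measured in peripheral blood mononuclear cells of 9 donors, 6 with high and 3 with low lipoprotein(a), Lp(a), an LDL-like particle that carries apolipoprotein(a). The cells of each donor were left untreated or stimulated for 2 h with lipopolysaccharide (LPS), the bacterial cell wall component sensed by Toll-like receptor 4. This gave 18 libraries in 4 groups. The labels put the LPS dose at 1 µg/ml in the treatment protocol and at 1 mg/ml in the sample characteristics, so the dose is uncertain by that factor. The libraries held 1890210 to 2839472 reads in genes (median 2254347). A gene with 3 reads stood at 1.06 to 1.59 CPM, reads scaled to a common library total. Levels are given as mean CPM ± SD over donors and changes as differences of log2(CPM + 1) ± SE, which understate the change of low genes. Floors cover counting error only. The share of mitochondrial ribosomal RNA was 7.05% to 15.3% in the high and 5.59% to 8.01% in the low Lp(a) libraries, and the share of ribosomal protein genes 8.65% to 14.2% and 9.46% to 20.7%. Low Lp(a) replicates 1 and 2 differed less from each other than any other pair within a group. The chi-square per degree of freedom of their reads over genes was 2.50 untreated and 6.81 with LPS, against 8.60 to 41.0 in the other 34 pairs. Counts without either of them, and with both counted as 1 donor, are given below where they move a result by over 1.5 times.

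**Figure D1:**
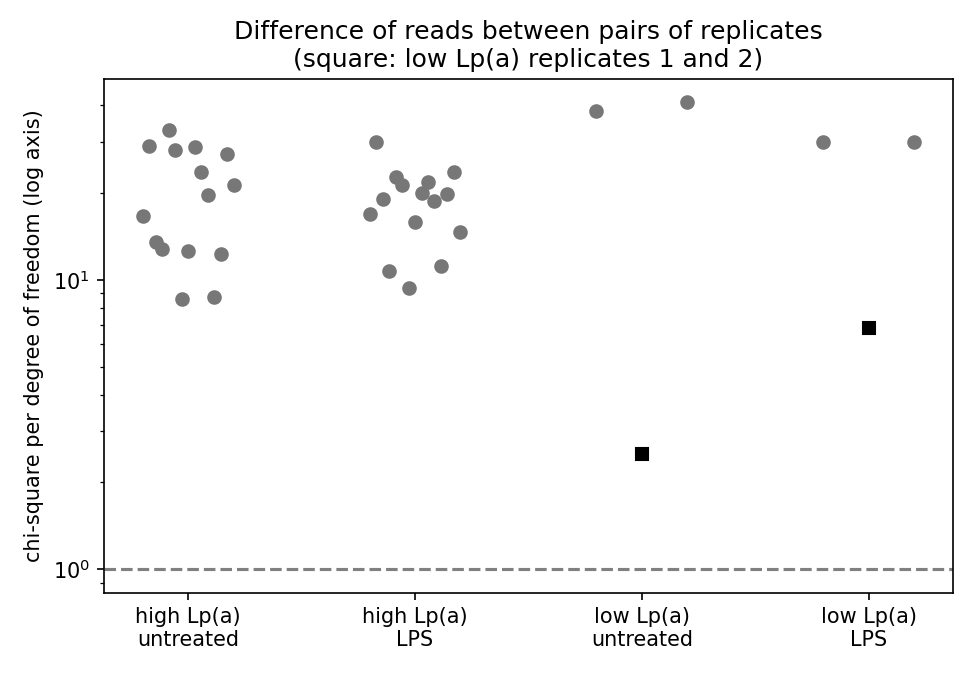
Chi-square per degree of freedom (log axis) of the reads over genes between each pair of replicates of a group; circles are pairs, squares are low Lp(a) replicates 1 and 2, and the dashed line at 1 is sampling noise. The squares stand at 2.50 and 6.81 and every circle at 8.60 or above.

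In cells of the high Lp(a) donors, LPS raised inflammatory cytokine genes. IL6, the gene of a cytokine of the acute phase response, went from 2.99 ± 4.77 to 85.8 ± 72.2 CPM (n = 6; log2 change 4.73 ± 0.66; limma with Benjamini-Hochberg, adjusted p = 5.10e-04; higher in 6 of 6 donors). PTGS2, which encodes the prostaglandin synthase COX-2, went from 67.1 ± 108 to 691 ± 471 CPM (4.77 ± 0.78). F3, which encodes tissue factor, the initiator of coagulation, rose from 15.1 ± 22.6 to 81.3 ± 77.6 CPM, in 5 of 6 donors (3.27 ± 0.75; limma adjusted p = 0.0451). C5AR1, the complement C5a receptor gene, fell from 91.8 ± 55.1 to 10.6 ± 5.97 CPM, and so did the chemokine receptor gene CCR1 (-2.83 ± 0.40), both in 6 of 6 donors.

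Of 17 cytokine genes measured, 7 rose and 10 did not pass, with 9 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.06e-27, and adjusted p = 0.0157 with an estimated correlation). IL1B, the interleukin-1 beta gene, rose by 4.14 on the log2 scale to 4451 ± 2722 CPM, IL1A by 4.13 and TNF by 2.42. Of 27 type I interferon response genes 7 rose, with 26 higher and 0 lower adjusted over the list alone, and 25 rose with the donor as a block (camera adjusted p = 0.0235 with an estimated correlation). Their median log2 change was 1.70, with IFI44L at 3.31, the antiviral gene MX1 at 2.75 and CMPK2 at 2.68. Of 19 chemokines 4 rose, with 7 higher and 1 lower adjusted over the list alone. CCL20 rose by 4.26, CXCL8, the neutrophil attractant, by 2.91, CCL3 by 3.94 and CCL4 by 3.20. CCL3 and CCL4 have near-identical copies, so their reads are uncertain. The chemokine list passed camera (adjusted p = 7.71e-09) but not with an estimated correlation (adjusted p = 0.252). Of 27 NF-kB factors and feedback genes 1 rose, TNIP3 (3.34), an inhibitor of NF-kB, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.11e-06, and adjusted p = 0.324 with an estimated correlation). Of 22 coagulation and fibrinolysis genes 2 rose, F3 and SERPINB2, the plasminogen activator inhibitor 2 gene (515 ± 605 to 1999 ± 1130.2 CPM; limma adjusted p = 0.0395). PLAUR, the urokinase receptor gene, changed by 1.20 (limma adjusted p = 0.994, and 0.00434 with the block).

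Scavenger receptor and cholesterol efflux genes fell in 2 of 19 cases, CD36 (-2.45) and MSR1 (-2.07), both receptors that take up modified LDL, with 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0235 with an estimated correlation). Adhesion and migration genes fell in 1 of 25 cases, CCR1, with 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0472 with an estimated correlation). Classical monocyte markers had a median of -1.03, with 1 of 14 lower, CD36, and 9 lower with the block. That list passed camera (adjusted p = 1.48e-10) but not with an estimated correlation (adjusted p = 0.0899), where it passed with the block (adjusted p = 0.00974). Non-classical monocyte markers had a median of -0.47 with 1 of 11 lower, the growth factor receptor gene CSF1R (-2.37; camera adjusted p = 0.0395, and adjusted p = 0.252 with an estimated correlation). The other large falls over all genes were DHRS9 (-3.61), TNS1 (-3.17) and GPNMB (-3.10). CD14, the LPS co-receptor gene, went from 47.5 ± 34.1 to 7.57 ± 6.52 CPM (limma adjusted p = 0.0617, and 8.53e-07 with the block). TLR4 changed by -1.18 (limma adjusted p = 0.541, and 6.06e-05 with the block). THBD (-0.67), IL10 (0.46), NLRP3 (0.47) and CCL2 (-0.02 ± 0.94) passed in neither fit, and CCL2 turned positive with other scalings.

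Over 17151 genes, limma called 99, 46 higher and 53 lower, and 1011 had an unadjusted p under 0.05. With the donor as a block it called 694, 289 higher and 405 lower, which held all 99. With the block, the called members of the lists were, higher and lower, 10 and 0 of cytokines, 8 and 2 of chemokines, 5 and 3 of coagulation, 1 and 1 of inflammasome, 0 and 3 of TLR4 signalling and 6 and 2 of NF-kB genes. They were 1 and 10 of adhesion, 1 and 2 of glycolysis, 1 and 9 of scavenger receptor, 1 and 2 of antigen presentation, 0 and 5 of non-classical monocyte, 0 and 1 of T cell and 1 and 0 of plasma cell genes. Camera called 8 of 26 lists without and 12 with the block. There TLR4 signalling (adjusted p = 0.0348), antigen presentation (0.0319), plasma cell (0.0374) and mitochondrially encoded genes (0.0155) also passed. None of these 4 did with an estimated correlation. Lists that did not pass camera without the block had median log2 changes of coagulation and fibrinolysis 0.04, inflammasome -0.11, TLR4 receptor and signalling -0.05, glycolysis 0.03, oxidative phosphorylation -0.03, sterol synthesis and LDL uptake -0.09, antigen presentation and costimulation -0.36, T cell markers -0.09, NK and cytotoxic cell markers 0.00, B cell markers 0.02, plasma cell markers 0.22, dendritic cell markers -0.14, platelet markers -0.01, neutrophil markers -0.25, erythroid markers 0.11, immediate early and heat shock genes -0.08, mitochondrially encoded genes 0.09 and proliferation genes 0.04. Neutrophil markers had 1 measured member. Median, mean and test differed in sign for inflammasome, glycolysis, oxidative phosphorylation, sterol synthesis and LDL uptake, NK and cytotoxic cell markers, B cell markers, platelet markers and immediate early and heat shock genes. The medians of TLR4 signalling, oxidative phosphorylation and platelet lists turned positive with median-of-ratios scaling. The count was 43, 38 and 58 without high Lp(a) replicates 2, 4 and 6, and 33 genes were called whichever high Lp(a) donor was left out.

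In cells of the low Lp(a) donors, LPS raised cytokine and interferon response genes. IL6 went from 1.62 ± 0.765 to 543 ± 329 CPM (n = 3; log2 change 7.50 ± 0.93; limma with Benjamini-Hochberg, adjusted p = 1.55e-04), and IL10, an anti-inflammatory cytokine, from 0.983 ± 0.852 to 21.5 ± 2.35 CPM (3.62 ± 0.51; limma adjusted p = 3.94e-04), both in 3 of 3 donors. CSF3, a granulocyte growth factor gene, was at 0 in every untreated library and at 71.3 ± 25.4 CPM with LPS, at least 48.5-fold higher against the floor of 3 reads per library. In the high Lp(a) donors CSF3 was also at 0 untreated and at 14.5 ± 8.85 CPM with LPS, at least 9.34-fold higher. F3 rose by 4.69 on the log2 scale (limma adjusted p = 0.0238).

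Of 27 type I interferon response genes 24 rose, with 27 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00914 with an estimated correlation). Their median log2 change was 3.71, with RSAD2 at 5.94, CMPK2 at 5.90 and IFIT1 at 5.35. Of 17 cytokines 11 rose, with 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00914 with an estimated correlation), among them IL36G (6.36), IL1B (4.37) and TNF (3.53). Of 19 chemokines 4 rose, with 13 higher and 1 lower adjusted over the list alone, and 15 rose with the block. CCL20 rose by 4.59, CXCL8 by 3.30, and CCL3 by 5.49 and CCL4 by 3.85, whose reads are uncertain. The chemokine list passed camera (adjusted p = 2.82e-16), with adjusted p = 0.134 with an estimated correlation and adjusted p = 0.0409 with that and the block. CCL2, the monocyte attractant gene, went from 32 ± 22.7 to 586 ± 174 CPM (limma adjusted p = 0.145, and 2.55e-11 with the block). NF-kB genes rose in 2 of 27 cases, TNIP3 (5.62) and IER3 (1.87), with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.01e-09, and adjusted p = 0.372 with an estimated correlation). In the coagulation list of 22, F3 and SERPINB2 (230.1 ± 97.1 to 3133 ± 82.3 CPM) were higher. The inflammasome list of 17 had IL1B higher and PYCARD, an inflammasome adaptor gene, lower (-2.04; camera adjusted p = 0.0411, and adjusted p = 0.534 with an estimated correlation), with 2 higher and 3 lower adjusted over the list alone.

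Adhesion and migration genes had PECAM1 lower (-2.28) and MMP1, at 0 in the untreated libraries, at least 1.74-fold higher against the floor, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.382 with an estimated correlation). Other called members that fell were PLIN2, a lipid droplet protein gene (-2.40), IFI30 (-2.03), CSF1R (-3.19), the dendritic cell marker CLEC10A (-2.15) and the B cell marker VPREB3, which is near the floor. Among the largest falls over all genes were KCNE3 (-3.66), DHRS9 (-3.55), FPR3 (-3.52) and TMEM51 (-3.36). Classical monocyte markers had a median of -0.92 with 0 of 14 past the threshold in limma, 7 lower with the block, and 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.534 with an estimated correlation). T cell markers had a median of -0.35 with 0 of 14 past the threshold and 2 lower with the block (camera adjusted p = 0.0349, and adjusted p = 0.571 with an estimated correlation). CD14 changed by -2.41 and NLRP3 by 1.32, past the threshold only with the block (limma adjusted p = 1.35e-04 and 0.0135). THBD (-1.36), PLAUR (1.12) and TLR4 (0.50) passed in neither fit.

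Over 17151 genes, limma called 251, 166 higher and 85 lower, and 1694 had an unadjusted p under 0.05. With the donor as a block it called 1330, 593 higher and 737 lower, which held all 251. With the block, the called members of the lists were, higher and lower, 13 and 0 of cytokines, 15 and 1 of chemokines, 27 and 0 of interferon response, 5 and 2 of coagulation, 4 and 3 of inflammasome, 2 and 2 of TLR4 signalling and 13 and 0 of NF-kB genes. They were 3 and 10 of adhesion, 2 and 4 of glycolysis, 0 and 2 of oxidative phosphorylation, 2 and 0 of sterol synthesis, 1 and 7 of scavenger receptor and 2 and 6 of antigen presentation genes. They were 0 and 5 of non-classical monocyte, 1 and 1 of cytotoxic cell, 0 and 2 of B cell, 1 and 0 of plasma cell and 1 and 0 of immediate early genes. The dendritic cell marker CLEC10A was lower with the block too. Camera called 8 of 26 lists without and 11 with the block. There scavenger receptor (adjusted p = 0.00615), non-classical monocyte (0.0189) and oxidative phosphorylation genes (0.049) also passed. None of these 3 did with an estimated correlation. Lists that did not pass camera without the block had median log2 changes of coagulation and fibrinolysis -0.03, TLR4 receptor and signalling -0.08, glycolysis -0.28, oxidative phosphorylation -0.24, sterol synthesis and LDL uptake -0.11, scavenger receptors and cholesterol efflux -0.51, antigen presentation and costimulation -0.44, non-classical monocyte markers -0.59, NK and cytotoxic cell markers -0.14, B cell markers -0.33, plasma cell markers 0.01, dendritic cell markers -0.03, platelet markers -0.11, neutrophil markers -0.95, erythroid markers -0.45, immediate early and heat shock genes -0.06, mitochondrially encoded genes -0.05 and proliferation genes 0.05. Median, mean and test differed in sign for coagulation and fibrinolysis, TLR4 receptor and signalling, sterol synthesis and LDL uptake, NK and cytotoxic cell markers, immediate early and heat shock genes and mitochondrially encoded genes. Median-of-ratios scaling moved the median of all genes from -0.11 to -0.0022, and the medians of the coagulation, TLR4 signalling, cytotoxic cell, dendritic cell, platelet, immediate early and mitochondrially encoded lists turned positive. The count was 54, 44 and 127 without low Lp(a) replicates 1, 2 and 3, 43 with replicates 1 and 2 counted as 1 (an alternative chosen after the data were seen), and 138 from the 6 low Lp(a) libraries alone. In all, 34 genes were called whichever low Lp(a) donor was left out.

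**Figure D2:**
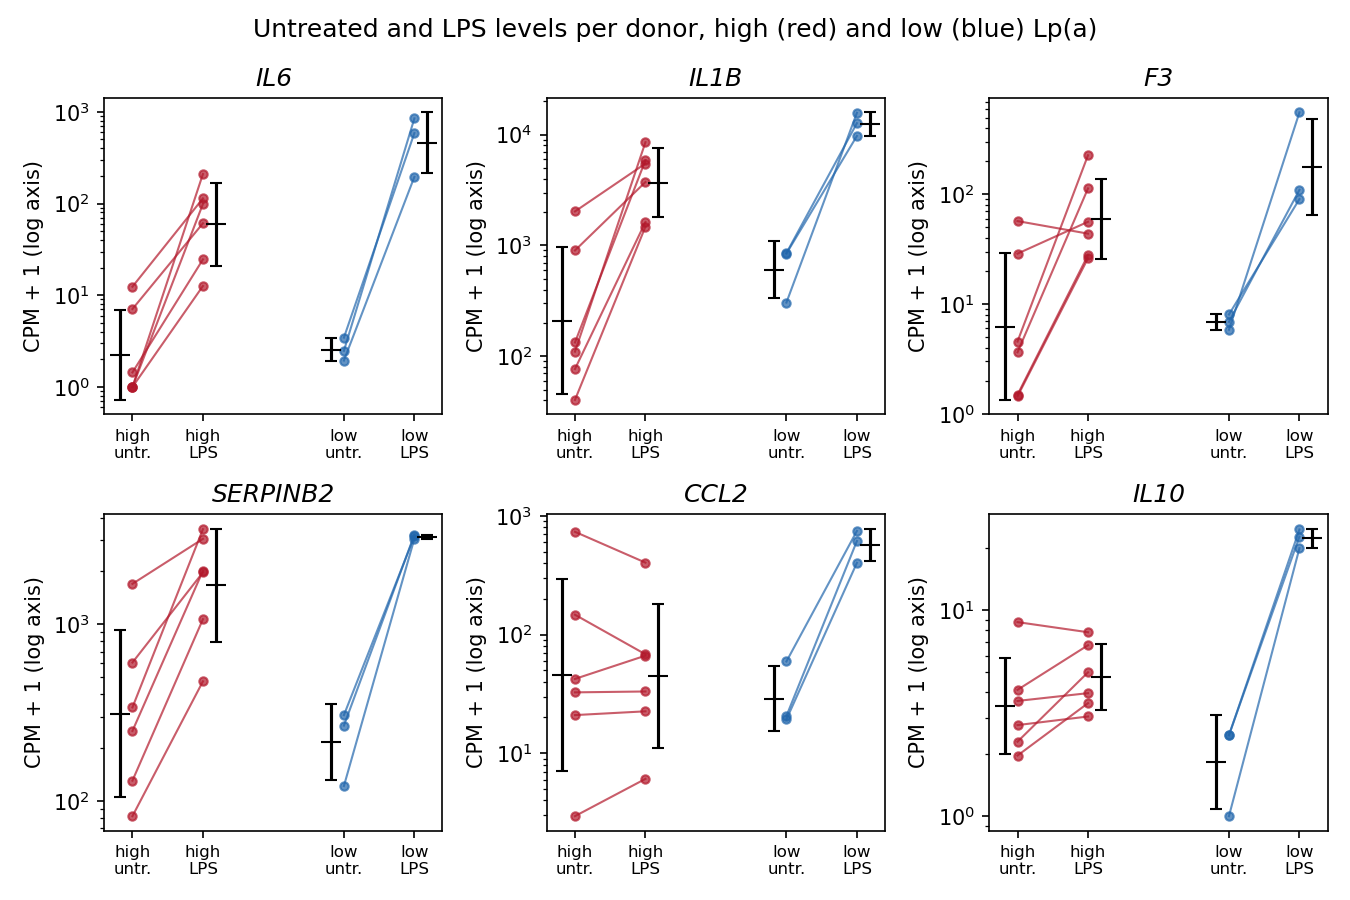
CPM + 1 (log axis) of 6 genes in the untreated and LPS libraries of each donor, high Lp(a) in red (n = 6) and low Lp(a) in blue (n = 3); lines join the libraries of a donor and black marks are the mean ± SD on the log2 scale. IL6 and IL1B were higher with LPS in all 9 donors, and CCL2 and IL10 in all 3 low Lp(a) donors.

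Of the 46 genes raised in high and 166 in low Lp(a) donors, 43 were in both lists, against 0.445 for independent lists. Of the 53 and 85 genes lowered, 27 were in both, against 0.263. The pair of comparisons have no library in common, but they share 1 estimate of the spread of each gene. The lists are therefore linked even without a common response, and the values for independent lists are too low as a reference. Across all 17151 genes the log2 changes correlated with r = 0.571 (Spearman's rho 0.341), and across the 280 genes called in either group with r = 0.917, with 98.9% of the same sign. Genes are not independent replicates, and the 280 were chosen by their change. Of the 280, 89.6% changed less in high Lp(a), where the median size was 1.13 against 2.19. Over all 17151 genes 68.6% did, with median sizes of 0.179 and 0.313, from 6 and 3 donors. Selection favours large changes in the smaller group. Of the 99 genes called in high Lp(a), 70.7% changed less there.

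**Figure D3:**
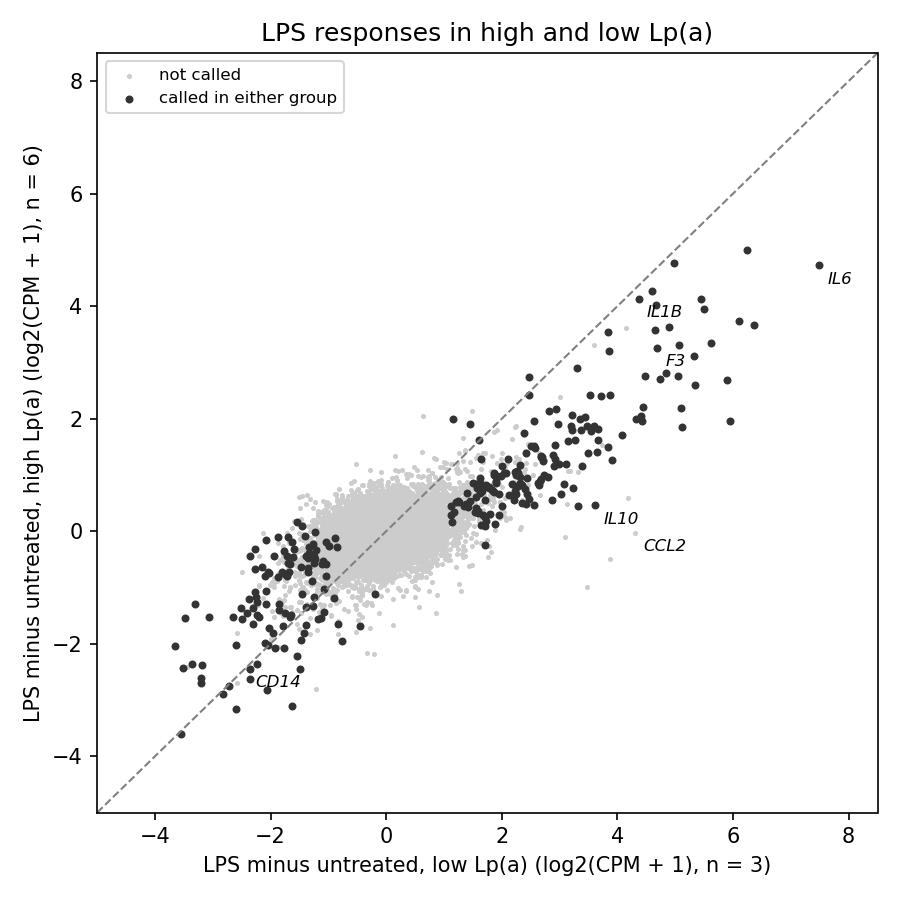
Change of log2(CPM + 1) with LPS of each of 17151 genes in low (x axis, n = 3) and high (y axis, n = 6) Lp(a) donors; dark points are the 280 genes called in either group and the dashed line marks equal change. Of these, 89.6% changed less in high Lp(a), and CCL2 lies near 0 on the y axis.

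Between untreated cells of high and low Lp(a) donors, 3 genes differed, each lower in high Lp(a). ALDH2, which encodes a mitochondrial aldehyde dehydrogenase, stood at 8.88 ± 3.3 CPM in high (n = 6) and 52.8 ± 8.98 CPM in low Lp(a) (n = 3; log2 difference -2.50 ± 0.33; limma with Benjamini-Hochberg, adjusted p = 0.0275). SNAI1, a transcription factor gene, stood at 2.37 ± 1.19 and 22.9 ± 9.24 CPM (-2.81 ± 0.41; limma adjusted p = 0.0408). TRH, the thyrotropin releasing hormone gene, stood at 0.298 ± 0.528 and 8.21 ± 3.16 CPM (-2.85 ± 0.39; limma adjusted p = 0.0275). For each of the 3, every high Lp(a) donor was below every low one.

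Over 17151 genes, 3031 had an unadjusted p under 0.05. The groups did not overlap for 1038 genes, where 2 of the 84 choices of 3 donors do so by chance. The nearest list members that did not pass were F5, a clotting factor gene (2.05; limma adjusted p = 0.0654), ITGB2 (-1.51), CLEC10A (-2.14), LYZ (-2.13), HLA-DPB1 (-1.24) and CD8B (-1.42). The genes followed in every comparison did not pass, with log2 differences of F3 -0.14, THBD -1.40, PLAUR -2.12, SERPINB2 0.54, IL1B -1.53, IL6 -0.19, TNF 0.29, IL10 0.91, CCL2 0.67, CXCL8 -1.23, NLRP3 -1.04, CD14 -0.88 and TLR4 -0.45. The sign turned in alternatives for F3, IL6, IL1B, CCL2, CXCL8, NLRP3, CD14 and TLR4. The median of all genes was 0.20 higher in high Lp(a) on the CPM scale and 0.03 after median-of-ratios scaling. Relative to the 0.20, classical monocyte markers had a median of -1.84, with 0 of 14 past the threshold and 0 higher and 7 lower adjusted over the list alone. Immediate early and heat shock genes stood at -1.28, antigen presentation genes at -0.87 with 0 higher and 7 lower adjusted over the list alone, cytotoxic cell markers at -1.01 with 0 higher and 3 lower adjusted over the list alone, and glycolysis genes at -0.78 with 0 higher and 4 lower adjusted over the list alone. The other lists stood at inflammatory cytokines -0.63, chemokines -0.91, coagulation and fibrinolysis -0.55, inflammasome -0.46, type I interferon response 0.31, TLR4 receptor and signalling -0.21, NF-kB factors and feedback -0.62, adhesion and migration -0.63, oxidative phosphorylation -0.38, sterol synthesis and LDL uptake -0.19, scavenger receptors and cholesterol efflux -0.08, non-classical monocyte markers -0.70, T cell markers 0.19, B cell markers 0.07, plasma cell markers -0.86, dendritic cell markers -0.11, platelet markers -0.90, neutrophil markers -1.11, erythroid markers 1.23, mitochondrially encoded genes -0.27 and proliferation genes 0.04. As donor means, immediate early and heat shock genes stood at 8.02 in low Lp(a) replicates 1 and 2. In replicate 3 they stood at 6.18, inside the 6.04 to 7.46 of the high Lp(a) donors. Glycolysis (6.16, 6.15 and 5.53, against 5.01 to 5.73) and platelet lists (3.76, 3.57 and 2.38, against 1.85 to 3.53) overlapped likewise. Antigen presentation (6.16 to 6.28, against 4.96 to 6.06) and classical monocyte lists (5.08 to 5.77, against 2.87 to 4.70) did not overlap. Of 26 lists 16 passed camera and 0 with an estimated correlation, where the lowest adjusted p was 0.227. Median, mean and test differed in sign for TLR4 receptor and signalling, sterol synthesis and LDL uptake, scavenger receptors and cholesterol efflux, B cell markers, dendritic cell markers and proliferation genes. Median-of-ratios scaling and quantile normalization each turned the medians of sterol synthesis, scavenger receptor and dendritic cell lists negative, and quantile normalization alone turned that of mitochondrially encoded genes positive. The count of 3 was 0 with the monocyte marker level of the donor as a covariate, 32 in edgeR, 0 with pseudocount 0.25, 8 with pseudocount 5, 6 without a filter, 1 with the stricter filter, 13 with median-of-ratios scaling, 25 with robust variances, 336 with a donor random effect, 0 with low Lp(a) replicates 1 and 2 counted as 1, 0 without low Lp(a) replicate 1 or 2 or high Lp(a) replicate 1, 2 or 3, 1 without high Lp(a) replicate 4, and 2004 without low Lp(a) replicate 3.

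After LPS, 213 genes differed between high and low Lp(a) donors, 8 of 17 cytokine genes among them, each lower in high Lp(a). IL10 stood at 4.03 ± 1.91 CPM in high (n = 6) and 21.5 ± 2.35 CPM in low Lp(a) (n = 3; log2 difference -2.24 ± 0.36; limma with Benjamini-Hochberg, adjusted p = 0.0243), with every high Lp(a) donor below every low one. IL1RN, the interleukin-1 receptor antagonist gene, stood at 513 ± 317 and 3452 ± 1516 CPM (-2.90 ± 0.49), and NLRP3, an inflammasome sensor gene, at 20.6 ± 8.53 and 71.9 ± 15.8 CPM (-1.88 ± 0.40), again without overlap. CCL2 stood at 98.9 ± 151 and 586 ± 174 CPM, with overlap of the groups (-3.66 ± 0.85; limma adjusted p = 0.0481). The monocyte alarmin genes S100A8 (-3.42 ± 0.68) and S100A9 (-3.42 ± 0.63) were lower too.

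Of the 213 genes, 122 were higher and 91 lower in high Lp(a), so 42.7% were lower, and 3946 had an unadjusted p under 0.05. Median-of-ratios scaling gave 23 higher and 149 lower, 86.6% lower, and edgeR 15 higher and 189 lower. The median of all genes was 0.23 higher in high Lp(a) on the CPM scale and 0.01 after median-of-ratios scaling. The groups did not overlap for 1842 genes, where 2 of 84 choices do so by chance. Relative to the 0.23, cytokines had a median of -2.48, with 0 higher and 13 lower adjusted over the list alone and TNFSF15 (-3.31) and INHBA (-3.07) among the called genes. Chemokines stood at -2.51, with 3 of 19 lower, CCL2, CCL3 (-2.08) and CCL4 (-2.06), and 0 higher and 16 lower adjusted over the list alone. Interferon response genes stood at -1.88, with 2 of 27 lower, IFIT2 (-2.25) and OASL (-1.72), and 0 higher and 23 lower adjusted over the list alone. NF-kB genes stood at -1.13, with 3 of 27 lower, DUSP2 (-1.87), DUSP1 (-1.68) and ATF3 (-1.60), and 0 higher and 16 lower adjusted over the list alone. Beside these, classical monocyte markers stood at -1.59, with 4 of 14 lower, S100A8, S100A9 and SERPINA1 (-2.50) among them, and 0 higher and 8 lower adjusted over the list alone. SERPINA1 is also the 1 called gene of the 22 in the coagulation list, which had 1 higher and 4 lower adjusted over the list alone. The inflammasome list had MEFV (-2.52), NLRP3 and CARD16 (-1.37) lower, and adhesion genes ITGAX (-1.67), ITGB2 (-1.51) and ITGAM (-1.46). Antigen presentation genes had HLA-DRA (-1.87), HLA-DPB1 (-1.11) and TNFSF9 (-2.09) lower, cytotoxic cell markers GZMA (-1.76) and CD8B (-1.50), sterol genes INSIG1 (-1.42) and scavenger receptors MARCO (-1.77), while the T cell marker TRAT1 was higher (0.96).

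The largest differences upward were SLC35E2A (3.05), GTF2IRD1 (2.47), the olfactory receptor pseudogene OR10AH1P (2.40), KANTR (2.38) and TPH1 (2.31), and IFITM3 was among the largest downward (-3.11). The remaining genes followed throughout did not pass, with log2 differences of F3 -1.56, THBD -0.71, PLAUR -2.05, SERPINB2 -0.92, IL1B -1.76, IL6 -2.95, TNF -0.82, CXCL8 -1.62, CD14 -0.89 and TLR4 -2.12. Of these, F3, THBD, SERPINB2, TNF and CD14 turned positive with the monocyte marker level of the untreated library as a covariate. The other lists stood, relative to the median of all genes, at coagulation and fibrinolysis -0.66, inflammasome -0.74, TLR4 receptor and signalling -0.22, adhesion and migration -0.65, glycolysis -0.65, oxidative phosphorylation -0.18, sterol synthesis and LDL uptake -0.39, scavenger receptors and cholesterol efflux -0.70, antigen presentation and costimulation -1.01, non-classical monocyte markers -0.58, T cell markers 0.41, NK and cytotoxic cell markers -0.97, B cell markers 0.53, plasma cell markers -0.94, dendritic cell markers -0.25, platelet markers -0.75, neutrophil markers -0.45, erythroid markers 1.80, immediate early and heat shock genes -1.23, mitochondrially encoded genes -0.19 and proliferation genes 0.17. Of 26 lists 18 passed camera and 0 with an estimated correlation, where the lowest adjusted p was 0.0609, for the cytokine, chemokine, inflammasome, NF-kB and adhesion lists. Median, mean and test differed in sign for TLR4 receptor and signalling, oxidative phosphorylation, dendritic cell markers and mitochondrially encoded genes, and the medians of TLR4 signalling, oxidative phosphorylation and mitochondrially encoded lists turned negative with median-of-ratios scaling. The count of 213 was 0 with the monocyte marker covariate, 23 with the untreated heat shock level as a covariate (chosen after the data were seen), 18 without a filter, 91 with pseudocount 0.25, 109 with quantile normalization, 418 with a donor random effect, 0 with low Lp(a) replicates 1 and 2 counted as 1, and 0 without either of them. It was 1277 without low Lp(a) replicate 3, and 10, 5, 650, 126 and 23 without high Lp(a) replicates 1 to 5.

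Whether the LPS response itself differed was tested as the change in high minus the change in low Lp(a) donors. Without the donor block limma called 0 genes, and with it 144, 15 higher and 129 lower. Of the 144, 133 changed less in high Lp(a), 108 of them in the same direction in both groups and 25 in opposite directions, and 11 changed more. Over all 17151 genes 68.6% changed less in high Lp(a), and choosing genes by their difference favours large changes in the smaller group. With the block, IL10 differed by -3.15 ± 0.48 on the log2 scale (n = 6 and 3; limma with Benjamini-Hochberg, adjusted p = 2.98e-04), as its level went from 2.92 ± 2.51 to 4.03 ± 1.91 CPM in high and from 0.983 ± 0.852 to 21.5 ± 2.35 CPM in low Lp(a). CCL2 differed by -4.34 ± 0.35 (limma adjusted p = 1.54e-08), and CCL7, another monocyte attractant gene, by -4.48 ± 0.35, as it went from 237 ± 326 to 104 ± 114 and from 32.3 ± 3.18 to 375 ± 73.1 CPM. For all 3, the change of every high Lp(a) donor was below that of every low one.

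With the block, 22 of 27 type I interferon response genes had the smaller change in high Lp(a), with 0 higher and 26 lower adjusted over the list alone (median -1.92; camera adjusted p = 0.0195 with an estimated correlation), among them the RNA sensor gene DDX58 (-2.23 ± 0.28). So had 6 of 17 cytokines, with 0 higher and 11 lower adjusted over the list alone (median -1.31; camera adjusted p = 0.046 with an estimated correlation). Of 19 chemokines 5 did, with 0 higher and 9 lower adjusted over the list alone (median -0.65; camera adjusted p = 4.98e-15, and adjusted p = 0.181 with an estimated correlation). TLR4 (-1.67; limma adjusted p = 0.00339; -1.18 in high and 0.50 in low Lp(a)), SCARB2 (-1.45), TNIP3 (-2.29) and PRF1, the perforin gene (-1.20), passed with the block as well, and so did the glucose transporter gene SLC2A1, with a positive difference of 1.08. Outside the interferon, cytokine and chemokine lists, the other members called with the block, named after their values were seen, were CD274 (-2.28), MMP19 (-1.95), CASP4 (-0.95) and PLIN2 (0.95). The remaining genes followed throughout passed in neither fit, at F3 -1.42, THBD 0.69, PLAUR 0.08, SERPINB2 -1.46, IL1B -0.23, IL6 -2.76, TNF -1.11, CXCL8 -0.40, NLRP3 -0.85 and CD14 -0.01. The sign turned in alternatives for PLAUR, IL1B, CXCL8 and CD14. PLAUR passed with the block at -1.16 (limma adjusted p = 0.00271) when the LPS effect could vary with the untreated immediate early and heat shock level, an alternative chosen after the data were seen.

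Without the block 541 genes had an unadjusted p under 0.05 and edgeR on the recovered reads called 0; with it 1588 had an unadjusted p under 0.05. The groups of donor changes did not overlap for 774 genes, where 2 of 84 choices do so by chance. Of 26 lists 6 passed camera without the block and 0 with an estimated correlation, and 7 and 2 with the block. Of those 7, the lists lost with an estimated correlation had, besides chemokines, adjusted p values of 0.393 for NF-kB factors and feedback, 0.447 for inflammasome, 0.447 for oxidative phosphorylation and 0.479 for T cell markers, with medians of NF-kB factors and feedback -0.30, inflammasome -0.38, oxidative phosphorylation 0.21 and T cell markers 0.27. The other lists had medians of coagulation and fibrinolysis 0.02, TLR4 receptor and signalling -0.01, adhesion and migration 0.05, glycolysis 0.23, sterol synthesis and LDL uptake -0.01, scavenger receptors and cholesterol efflux -0.09, antigen presentation and costimulation 0.03, classical monocyte markers -0.10, non-classical monocyte markers 0.26, NK and cytotoxic cell markers 0.11, B cell markers 0.34, plasma cell markers 0.17, dendritic cell markers 0.01, platelet markers 0.14, neutrophil markers 0.69, erythroid markers 0.60, immediate early and heat shock genes -0.09, mitochondrially encoded genes 0.14 and proliferation genes 0.04. Median, mean and test differed in sign for coagulation and fibrinolysis, adhesion and migration and antigen presentation and costimulation, and median-of-ratios scaling turned the medians of coagulation, adhesion, antigen presentation, dendritic cell and proliferation lists negative. The blocked count of 144 was 53 without a filter, 75 with low Lp(a) replicates 1 and 2 counted as 1, 84 and 57 without each of them, and 22 with the LPS effect allowed to vary with the untreated monocyte marker level. In all, 51 genes were called whichever donor was left out.

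As a mean over the list in each donor, interferon response genes changed with LPS by 1.72 ± 0.58 in high (SD, n = 6) and 3.77 ± 0.11 in low Lp(a) (n = 3), two-sided exact permutation p = 0.0119, adjusted 0.103 over 26 lists. The 0.0119 is the smallest p that 84 choices can give. Cytokines changed by 2.16 ± 0.70 in high (SD, n = 6) and 3.59 ± 0.68 in low Lp(a) (n = 3) (exact permutation p = 0.0238, adjusted 0.155), and chemokines by 1.20 ± 0.90 in high (SD, n = 6) and 2.75 ± 0.29 in low Lp(a) (n = 3) (exact permutation p = 0.0476, adjusted 0.177). In high Lp(a) replicates 3 and 6, chemokines already stood at 6.30 and 5.29 untreated, above the 4.34 to 4.46 in low Lp(a). They changed there by 0.15 and 0.08. The other high Lp(a) donors changed by 1.43 to 2.34, still below the 2.43 to 2.98 in low Lp(a). Cytokines likewise stood at 4.94 and 4.33 untreated in these replicates, above the 3.29 to 4.09 in low Lp(a). They changed by 1.31 and 1.77, against 1.85 to 3.10 in the other high Lp(a) donors. After LPS, cytokines stood at 5.48 ± 0.84 in high (SD, n = 6) and 7.39 ± 0.25 in low Lp(a) (n = 3) (exact permutation p = 0.0119, adjusted 0.0619). No list passed the adjustment for the untreated level, the LPS level or the change, but with median-of-ratios scaling 7 passed for the LPS level. Plasma cell markers untreated, alone at the smallest p of that measure, were adjusted to 0.31. A list could thus pass only where several reached the smallest p together, so not passing does not speak against a difference.

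**Figure D4:**
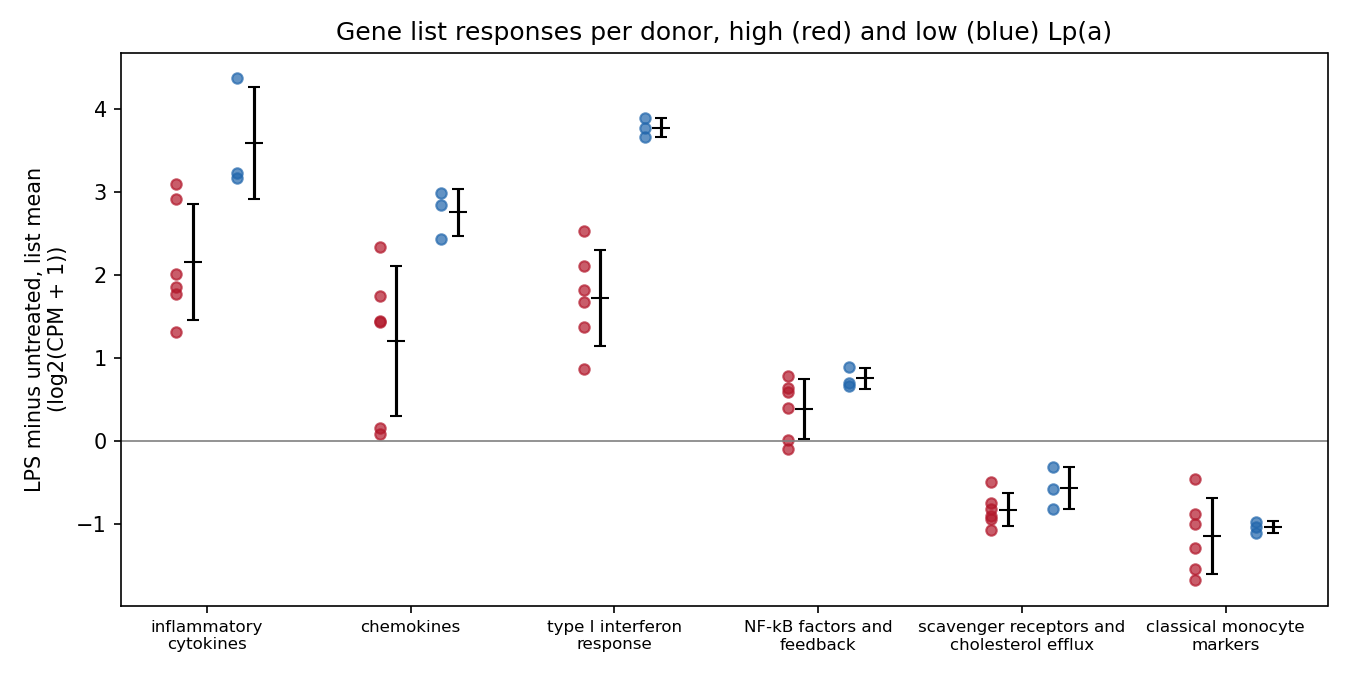
Mean over each gene list of the change of log2(CPM + 1) with LPS, 1 point per donor, high Lp(a) in red (n = 6) and low Lp(a) in blue (n = 3), with mean ± SD in black. For type I interferon response genes the 6 high Lp(a) donors lie below the 3 low ones (means 1.72 and 3.77).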

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

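The tests of low Lp(a) replicates 1 and 2 as 1 donor, of the heat shock covariate, of the blocked difference of responses as a result of its own, of the size of the lower levels after median-of-ratios scaling, and of both explanations for the likeness of that pair were chosen after the result was seen. For the covariate tests, the bound, 50% of the difference kept, was set before the values were seen for the monocyte markers. The margin by which a value must clear it was 2 standard errors at first and was lowered to 1 after the values were seen. It is the median standard error of single genes, not that of the median over them. Of 92 groups checked, 6 held a sample far from the others, where chance gives about 1 in 20.

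In high Lp(a) replicate 3 the mean log2(CPM + 1) of mitochondrially encoded genes was 10.33 untreated (11.15 to 11.52 in the other 5) and 10.60 with LPS (11.19 to 11.51). Mitochondrial messenger RNA made up 2.26% of its untreated library, against 3.91% to 4.83%. Haemoglobin genes made up 0.0733% of its untreated library (0.00182% to 0.0225% in the others) and 0.0806% of its LPS library (0.00185% to 0.0257%). In high Lp(a) replicate 5, T cell markers changed with LPS by -0.34 (-0.16 to -0.06 in the others).

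The LPS response of high Lp(a) donors differed from that of low ones, by a test of the difference, for 144 genes with the donor block and for 6 lists in camera without it. The medians of the difference were -1.31 for cytokines, -0.65 for chemokines, -0.38 for inflammasome, -1.92 for interferon response, -0.30 for NF-kB and 0.21 for oxidative phosphorylation genes, none of which passed with an estimated correlation without the block. With the block 2 did, the interferon response (adjusted p = 0.0195) and cytokine (adjusted p = 0.046) lists.

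The first pattern is this difference of the responses, in which 133 of the 144 genes changed less in high Lp(a) and 11 more. Of all 17151 genes 68.6% changed less there, and the 144 were chosen by their difference. Over the size of the difference of the 144, the untreated heat shock level of the donor as a covariate kept 96.3% of the median difference (1.5 to 1.45, median SE 0.29 to 0.31, 99 of them still called). This argues against the part of stress that this score measures as the whole cause. The score overlapped between the groups (8.02, 8.02 and 6.18 in low, 6.04 to 7.46 in high Lp(a)). Stress that it does not measure was not tested. With low Lp(a) replicates 1 and 2 as 1 donor, 75 genes were called, as counting a pair of like samples as separate donors would give, but all 144 kept their sign and the median difference was 99.9% of its size, with the median SE at 0.33 against 0.29. That the pair adds calls by its likeness therefore stays open. The monocyte marker covariate kept 83.4% of the difference (1.5 to 1.26, all 144 of the same sign), which clears the bound of 0.75 by 0.50, against a median SE of 0.39. The value clears the margin of 1 standard error set after the values were seen, but not the first margin of 2. Fewer monocytes in the high Lp(a) donors, as far as these markers measure them, therefore stay open as a cause. Only 19 of the 144 were still called, as the difference shrank and its median SE grew from 0.29 to 0.39. A difference that comes with Lp(a) may remain as a hypothesis, untested against other differences between these donors.

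The next pattern is the likeness of low Lp(a) replicates 1 and 2. One library entered 2 times is argued against by a chi-square per degree of freedom of 2.50 between their untreated reads, above sampling noise. Cells of the same donor in both could not be told apart from cells of different donors: T cell receptor segments gave 1.67 untreated, inside the range of a donor's own untreated and LPS libraries (0.50 to 2.06) and also inside that of different donors (1.08 to 6.65, median 3.65). With LPS the pair gave 1.57, against 0.809 to 8.15. Immunoglobulin segments had at most 25 reads in a library and were not used. No biological explanation was tested.

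The last pattern is the lower levels after LPS in high Lp(a). Over the 91 lower genes median-of-ratios scaling gave 112.4% of the median difference (-1.82 to -2.05, median SE 0.38 before and after, 90 of them still called). That scaling lowered the median of all genes as well, from 0.23 to 0.01, so a smaller difference could not have come out. The test therefore cannot decide on CPM scaling as the source of the lower values. The lower values were present under both scalings. The share of lower genes among those called rose by 43.9 percentage points, from 42.7% to 86.6%, but that scaling moves all genes of a library alike (median of all genes 0.23 to 0.01), so the rise was built in and leaves the part of library composition open; the count of higher genes depends on the scaling. The heat shock covariate kept 88.5% (-1.82 to -1.61, all 91 of the same sign, median SE 0.38 to 0.42), which clears the bound of -0.91 by 0.70. That passes the margin of 1 standard error but not the first margin of 2, so stress of the untreated cells stays open as a cause. Only 6 of the 91 were still called, as the difference shrank and its SE grew. With low Lp(a) replicates 1 and 2 as 1 donor, limma called 0 genes (2467 with an unadjusted p under 0.05), so no call held. The median difference of the 91 was -1.81 with a median SE of 0.43. Counting the pair as 1 also leaves fewer low Lp(a) donors, and the count was 10 and 5 without high Lp(a) replicates 1 and 2. Whether the pair adds calls by its likeness therefore stays open. Fewer monocytes in the high Lp(a) donors remain open: the monocyte marker covariate kept 72.2% of the median difference (-1.82 to -1.32), which clears its bound of -0.91 by 0.41, less than the median SE of 0.47 (0.38 before), and 0 genes were called. A difference that comes with Lp(a) may also account for them and was not tested apart from these.

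Other splits of the same samples were tested for each count. For LPS in high Lp(a), 3 of 100 splits gave as many genes as the real 99, with 340 as the highest other. Among the 32 splits that part the libraries of every donor, 1 did, the real one, with 0 as the highest other. This excludes chance, while the 340, from a split that does not part every donor's libraries, points to a structure of the samples besides LPS. For LPS in low Lp(a) there are only 10 splits, too few to exclude chance; the real 251 was reached by 1 of them and the highest other was 10. For high against low Lp(a) untreated, 6 of 84 choices gave at least 3 genes, the highest other 1876, so chance is not excluded and the samples have a structure of their own that is larger than the groups. With LPS 1 of 84 gave at least 213, the highest other 203. The real count stands first by little, and 0 of the 213 genes were called whichever donor was left out. Chance is therefore not excluded even if low Lp(a) replicates 1 and 2 are separate donors. With both as 1 the real count is 0, which all 28 choices of 2 of 8 donors reach by construction (the highest other 19), so nothing is decided for that case. For the difference of responses, the real count in limma without the block is 0, which all 84 reach by construction, the highest other 0, so nothing is decided, while 541 had an unadjusted p under 0.05 and edgeR called 0. With the block 1 of 84 gave at least 144, the highest other 38, and with low Lp(a) replicates 1 and 2 as 1, 1 of 28 gave at least 75, the highest other 73. The real choice thus stood well above every other for the 144. Low Lp(a) replicates 1 and 2 are alike even if they are separate donors, and few of the 84 choices hold both. The rank of 1 in 84 therefore overstates the evidence. The blocked difference was also made a result of its own after the data were seen, so chance is not excluded for the 144. With both as 1, another choice gave nearly as many genes, 73 against 75, in a setting chosen after the data were seen. Chance is not excluded there either.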

How the results depend on the processing

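Low Lp(a) replicates 1 and 2 as 1, the heat shock covariate and the alternatives of the blocked difference were chosen after the data were seen. The count for LPS in high Lp(a) (99) was 694 with the donor block and 38 to 93 without a donor. That for LPS in low Lp(a) (251) was 1330 with the block, 138 with the libraries compared only, 43 with low 1 and 2 as 1, and 44 to 127 without a donor. For high against low untreated (3) it was 0 with pseudocount 0.25, 8 with pseudocount 5, 6 without a filter, 1 with the stricter filter, 13 with median-of-ratios, 25 with robust variances, 32 in edgeR, 336 with a donor random effect, 0 with the monocyte covariate, 0 with low 1 and 2 as 1, and 0 to 2004 without a donor. For high against low with LPS (213) it was 91 with pseudocount 0.25, 18 without a filter, 109 with quantile normalization, 418 with the random effect, 0 with the monocyte covariate, 23 with the heat shock covariate, 0 with low 1 and 2 as 1, and 0 to 1277 without a donor. The difference of responses (0) was 144 with the block and 0 in the others. Its blocked count (144) was 53 without a filter, 22 with the monocyte covariate, 75 with low 1 and 2 as 1, and 57 to 167 without a donor. Lists passing camera (8, 8, 16, 18 and 6 in the order of the report) were 4, 2, 0, 0 and 0 with an estimated correlation and 4, 3, 1, 9 and 0 in fry. The correlation of responses (0.571) was 0.699 with pseudocount 5 and 0.469 to 0.575 without a donor. Donor list scores passing for the LPS level (0) were 7 with median-of-ratios. With LPS, leaving out low 1 or 2 gave 0 and low 3 gave 1277, so which donor is left out matters beside how many; more genes tested may explain 18 and 53 without a filter, and for the others the cause was not tested. Reversed log2 values came from genes that did not pass: for LPS in high Lp(a), CCL2 0.015 (pseudocount 0.25), 0.046 (median-of-ratios), 0.017 (quantile), -0.24 to 0.19 without a donor. Untreated: F3 0.21 (pseudocount 5), 1.09 (edgeR), 2.27 (monocyte covariate), 1.27 (heat shock covariate), -0.78 to 0.28 without a donor; IL1B 0.46 (monocyte covariate), 0.15 (heat shock covariate); IL6 0.098 (pseudocount 5), 0.60 (edgeR), 0.92 (monocyte covariate), 0.84 (heat shock covariate), -0.68 to 0.045 without a donor; CCL2 -0.13 to 1.47 without a donor; CXCL8 0.79 (monocyte covariate); NLRP3 0.14 (heat shock covariate); CD14 1.26 (monocyte covariate), -1.40 to 0.083 without a donor; TLR4 1.00 (monocyte covariate). With LPS: F3 0.15 (monocyte covariate); THBD 0.37 (monocyte covariate); SERPINB2 0.50 (monocyte covariate); TNF 0.40 (monocyte covariate), -1.37 to 0.19 without a donor; CD14 0.11 (monocyte covariate). For the difference of responses: PLAUR -0.20 (edgeR), -0.30 (low 1 and 2 as 1), -0.32 to 0.84 without a donor; IL1B 0.035 (quantile), -0.66 to 0.43 without a donor; CXCL8 -0.75 to 0.10 without a donor; CD14 0.21 (pseudocount 5), 0.16 (edgeR), 0.22 (low 1 and 2 as 1), -0.49 to 0.26 without a donor. For its blocked fit: PLAUR -0.41 (monocyte covariate), -1.16 (heat shock covariate), -0.30 (low 1 and 2 as 1), -0.32 to 0.84 without a donor; IL1B 0.035 (quantile), -0.66 to 0.43 without a donor; CXCL8 -0.75 to 0.10 without a donor; CD14 0.21 (pseudocount 5), 0.048 (edgeR), 0.22 (low 1 and 2 as 1), -0.49 to 0.26 without a donor. Only the PLAUR value of -1.16 passed its test, at an adjusted p of 0.00271. The cause of the reversals was not tested. Of 544 values for LPS in high Lp(a) 468 kept direction and side of the threshold, of 614 in low Lp(a) 492, of 483 untreated 399, of 1110 with LPS 710, and of 380 and 400 for the difference without and with the block 352 and 337. Depth limits genes under 1.06 to 1.59 CPM, the value of 3 reads.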

Other observations

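The tests here were set before the data were examined, but the lists and genes described were picked after their values were seen. Untreated, glycolysis genes scored 5.26 ± 0.34 in high (SD, n = 6) and 5.94 ± 0.36 in low Lp(a) (n = 3) (exact permutation p = 0.0476, adjusted 0.371), and plasma cell markers 2.88 ± 0.23 in high (SD, n = 6) and 3.5 ± 0.20 in low Lp(a) (n = 3) (exact permutation p = 0.0119, adjusted 0.31). The glycolysis score was 6.16 and 6.15 in low Lp(a) replicates 1 and 2. It was 5.53 in replicate 3, below high Lp(a) replicates 3 (5.66) and 6 (5.73). HK2, which encodes a hexokinase of glycolysis, stood at 65.2 ± 78.7 CPM untreated in high and 956 ± 808 CPM in low Lp(a), and at 23.1 ± 22.1 and 159 ± 116 CPM with LPS. LDHA, the lactate dehydrogenase A gene, stood at 399 ± 119 and 777 ± 17.3 CPM untreated (limma adjusted p = 0.131). B cell markers changed with LPS by -0.04 ± 0.07 in high (SD, n = 6) and -0.44 ± 0.18 in low Lp(a) (n = 3) (exact permutation p = 0.0119, adjusted 0.103), and erythroid markers by 0.11 ± 0.17 in high (SD, n = 6) and -0.50 ± 0.20 in low Lp(a) (n = 3) (exact permutation p = 0.0119, adjusted 0.103). None of these passed the adjustment over 26 lists, which a list at the smallest p cannot pass unless several others reach it too. LSS, a sterol synthesis gene, went from 2.04 ± 1.16 to 7.24 ± 1.77 CPM in low Lp(a), past the threshold only with the block (limma adjusted p = 0.0904, and 0.0159 with the block), and CD38 from 8.85 ± 4.35 to 28.1 ± 19.3 CPM in high and from 10.1 ± 3.71 to 50.9 ± 35 CPM in low Lp(a), likewise only with the block (0.00816 and 8.20e-04).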
